A study of Mus musculus with 4 samples.

How the data were processed

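Tumours of the colon were raised in female C57BL/6 mice with azoxymethane and dextran sulphate sodium, digested with collagenase and sorted on CD45 and EPCAM antibodies, per the labels' protocols. Cells were captured with a droplet 3′ kit (10x Genomics, V3), which counts UMIs, tags that mark single molecules, near the 3′ end of polyadenylated transcripts. Per the submitters' processing notes and the file header, the deposited values are raw UMI counts per gene and cell made by the authors with Cell Ranger 3.0.2 against the mouse build mm10. The annotation release is not given in the sources used here, nor is whether libraries were brought to equal depth. Every deposited barcode held at least 500 UMIs.

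The counts came as 1 matrix over barcodes with 4 suffixes. The labels name 4 samples, and no source used here pairs suffixes with them, so no library was assigned to a genotype or a sort and no comparison between the labelled groups was made. Where values by library are printed, each stands alone and none are averaged. The labels describe the sorted suspensions as loaded into 1 well, and also give each sample an index of its own, so how far a suffix matches a sample is itself unclear.

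Cells were kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. The filter passed 14198 of 18026 barcodes and removed 59.0, 56.3, 8.75 and 4.45% of libraries 1, 2, 3 and 4, with 44.5, 40.0, 8.73 and 4.39% above the mitochondrial limit. Scrublet, run per library in scanpy 1.11.5 with an expected doublet rate of 6%, marked 62 cells (0.437%), too few for the caller to have worked, and these were removed. An alternative removed the 625 highest-scoring cells, at 0.8% per 1000 cells. The kept cells of libraries 1 to 4 had medians of 4507, 3379, 4910 and 5176 UMIs, and haemoglobin took 8.90, 0.984, 0.001 and 0.021% of their UMIs.

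Counts were scaled to 10000 per cell and log-transformed, and cells were clustered on 2000 variable genes, 30 principal components and 15 neighbours by the Leiden method at resolution 1 (igraph 0.11.9). Fixed list genes, ribosomal, mitochondrial, haemoglobin, immunoglobulin, Y-linked and Xist genes, and V, D and J genes of the T cell receptor, were kept out of the clustering features. Constant genes of the T cell receptor, some of which are also T cell markers, were not kept out. A cluster took its name from 1 of 23 marker lists, written with "-like", when its score was at least 2 on the log2 scale, led by 1.5 the unrelated lists that met the same limits, and at least 3 markers and 50% of the list were seen in at least 10% of cells. Goblet, enteroendocrine and tuft lists gave the class name epithelial, and lymphatic endothelial gave endothelial. Regulatory T, CD8 T, gamma-delta T and innate lymphoid (ILC) lists gave T. Clusters whose markers pointed to several classes, or with a median depth below their libraries' depth divided by 3 and no marker of the name among their 10 leading genes, stayed unnamed. The score, margin and detection limits were set after the data had been opened, and after clusters were seen the rule was added that an erythroid name needs an erythroid marker among the leading genes, so an erythroid score without one did not count against another name. A class needed at least 50 cells.

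Raw counts were summed per class and divided by the class total to give CPM. With 1 matrix and no replicates, p-values were not computed. CPM carries an exact 95% Poisson interval, a share of cells an exact binomial one, and a log2 fold a range over 1000 Poisson redraws, all covering counting error only. Where 0 UMIs were seen, the level that 3 counts allow is given. A log2 fold compares the class with the unweighted mean of the other named classes after adding 1 CPM. For a list, the median log2 fold was ranked among 10000 random lists of the same size matched in 50 bins of expression, and a list is said to stand apart outside the central 95% of these. A gene was counted as at least 2-fold higher with at least 10 UMIs in the class, which leaves out members only in the stromal cluster, where both counts are given. As lower it needed 10 UMIs in the other class where 2 classes were set against each other, and no minimum otherwise. A log2 fold within a library uses only the named classes with at least 50 cells there. In libraries 1 and 2 these were epithelial-like and neutrophil-like cells alone, and mast-like cells reached that number in no library, so a library value is a narrower comparison than the pooled one. To compare shares of cells across depths, cells were thinned to 1000 UMIs.

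The 16 gene lists (208 genes) covered EGFR family receptors and feedback, EGFR ligands and sheddases, the IL-1 and IL-6 families, myeloid immune suppression, antigen presentation, chemokines, T cell checkpoints, T cell effectors, matrix and fibroblast genes, Wnt targets, absorptive differentiation, interferon response, angiogenesis, proliferation and dissociation stress. The lists, their classes, the tests and most alternatives were fixed before the data were examined. Named genes were Egfr and each member of the EGFR lists with at least 10 UMIs in some class, and Il1b, Il6, Il10, Tgfb1, Cd274, Arg1 and Vegfa. For each other list up to 4 members were named, those with the largest log2 fold among genes with at least 10 UMIs, at least 2-fold above the others and above them in each library that gives a value, with the member of lowest fold. The 5 leading genes of a cluster serve only as description.

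Alternatives covered the cell filter (500 genes, 1000 UMIs and 10% mitochondrial), doublets kept, resolutions of 0.5 and 2, 4000 variable genes, list genes as features, 0.1 or 10 CPM added, totals without the 50 most abundant genes of each class, only list genes with a mean of at least 10 UMIs over the classes compared, all other cells summed, each library left out and thinning. Gene positions come from GENCODE vM21 on the same build, to which 30934 of 31053 gene identifiers matched and 119 did not. In data simulated for 8725 genes of the class comparison, the direction was recovered for 100% of genes changed by log2 1, 2 and 3 (68, 66 and 66 genes), and their intervals held the true value for 97.1, 90.9 and 93.9%. Of 8525 unchanged genes 0% lay 2-fold off, while 8.0% of 200 unchanged lists were said to stand apart, more than the 5% meant. The simulation drew Poisson counts, as the intervals assume, from 1 profile shared by all classes. It used only genes with at least 3 counts expected in the smallest class, which leaves out Egfr. It therefore does not test genes of low count or spread between cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.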

Results

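The data are single-cell RNA counts from colon tumours of female C57BL/6 mice. The tumours were induced with the carcinogen azoxymethane (12.5 mg/kg) and 3 cycles of the colitis agent dextran sulphate sodium (2.5% in the first pair of cycles and 2% in the last), and were taken 30 days after the last cycle. The labels name 4 samples in 4 groups of 1 sample each: CD45-positive (immune) and CD45-negative cells, each from mice lacking Egfr in the myeloid lineage and from Egfr fl/fl controls. The series asks how myeloid loss of the receptor alters the immune and non-immune cells of such tumours. The deposited counts form 1 matrix of 31053 genes and 18026 barcodes with 129529250 UMIs (unique molecules). The barcodes end in 1 of 4 numbers, and no source used here pairs a number with a sample. The genotype comparison and the sort comparison were therefore not made. Barcodes sharing a number are treated as an unassigned library, and the comparisons are between cell classes of the pooled matrix. Libraries 1, 2, 3 and 4 held 9246770, 17158831, 37642375 and 65481274 UMIs in 1449, 3902, 4949 and 7726 barcodes, of which 594, 1699, 4463 and 7380 were kept. As 1 pooled matrix has no replicate, no p-value is given, and all intervals are 95% intervals for counting error only.

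Egfr (ENSMUSG00000020122), the epidermal growth factor receptor and the gene deleted in the myeloid lineage, was found chiefly in epithelial-like cells. Its level there was 20.4 CPM (UMIs of the gene scaled to the class total; exact Poisson interval 18.4 to 22.7) against a mean of 0.913 CPM over the other named classes, a log2 fold of 3.49 (3.07 to 3.96). An unnamed stromal cluster of 83 cells, which carried fibroblast and endothelial markers, had 23.5 CPM (10.2 to 46.4) from 8 UMIs, and plasmacytoid-dendritic-like cells had 7.45 CPM (3.41 to 14.1) from 9 UMIs. Monocyte/macrophage-like cells held 2 Egfr UMIs in 2556 cells, or 0.0599 CPM (0.0073 to 0.216). In neutrophil-like cells 3 UMIs were counted in 2648 cells, or 0.350 CPM (0.0722 to 1.02). Both myeloid levels lay below the epithelial-like interval. The labelled samples include mice lacking Egfr in the myeloid lineage, and their share of these pooled cells is unknown. Neither value is therefore a level of myeloid cells with the gene intact. The 358 epithelial-like UMIs fell to libraries 1, 2, 3 and 4 as 141, 210, 1 and 6.

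In monocyte/macrophage-like cells of libraries 1, 2 and 3 there were 0 Egfr UMIs in 10, 13 and 674 cells, which allow up to 18.3, 47.0 and 0.302 CPM. Library 4 had 2 UMIs in 1859 such cells, or 0.086 CPM (0.01 to 0.311). Neutrophil-like cells of libraries 1 and 3 had 0 UMIs in 78 and 501 cells, allowing up to 9.18 and 1.42 CPM. Library 2 had 1 UMI in 272 neutrophil-like cells, or 2.60 CPM (0.066 to 14.5), and library 4 had 2 in 1797, or 0.348 CPM (0.042 to 1.26). Egfr spans positions 16752203 to 16918158 of chromosome 11 on the forward strand of mm10, with up to 28 exons in an annotated transcript. The assay reads tags near the 3′ end of a transcript, which need not tell a deleted from an intact allele, so these counts check no label.

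An Egfr UMI was seen in 12.9% of epithelial-like cells (exact binomial interval 11.4 to 14.5; median depth 5090.5 UMIs). Among 1569 B-like cells, a type in which little Egfr is known, there were 0 UMIs, allowing up to 0.455 CPM at a median depth of 4014.0 UMIs. After each cell was thinned to 1000 UMIs the share was 3.50% (2.63 to 4.55) of 1516 epithelial-like cells, with 276 shallower cells left out. It was 0 of 1489 B-like cells, allowing up to 0.202%, with 80 left out. In thinned monocyte/macrophage-like cells it was 0 of 2535, allowing up to 0.118%. Epithelial-like Egfr kept its direction under every alternative run, but its log2 fold over the other classes lay between 1.48 with 10 CPM added before the log and 4.42 after thinning. Under the stricter cell filter Egfr in epithelial-like cells was 11.6 CPM and its log2 fold was 2.62.

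The 14136 kept cells formed 30 clusters, and 12505 cells (88.5%) lay in clusters named by fixed markers. Neutrophil-like cells were 18.7% of kept cells (18.1 to 19.4), monocyte/macrophage-like 18.1% (17.5 to 18.7), T-like 16.4% (15.8 to 17.01), epithelial-like 12.7% (12.1 to 13.2) and B-like 11.1% (10.6 to 11.6). Dendritic-like cells made up 5.70%, plasma-like 3.20%, erythroid-like 1.11%, plasmacytoid-dendritic-like 0.906% and mast-like 0.559%. The unnamed stromal cluster held 0.587% of cells. The sort was made on CD45 and EPCAM, so these shares describe sorted cells, not the tumour. A cluster of 399 cells led by Gm26917 and Lars2 was named epithelial-like although the erythroid markers, a sign of red cell RNA, scored higher in it (7.43) than the epithelial ones (5.18). In another epithelial-like cluster, of 627 cells led by Saa1 and Lypd8, they scored 6.23 against 6.56. Together these held 1026 of the 1792 epithelial-like cells. With both left unnamed, an alternative chosen after seeing the data, the epithelial-like share was 5.42% and Egfr there 14.0 CPM, a log2 fold of 2.97.

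**Figure D1:**
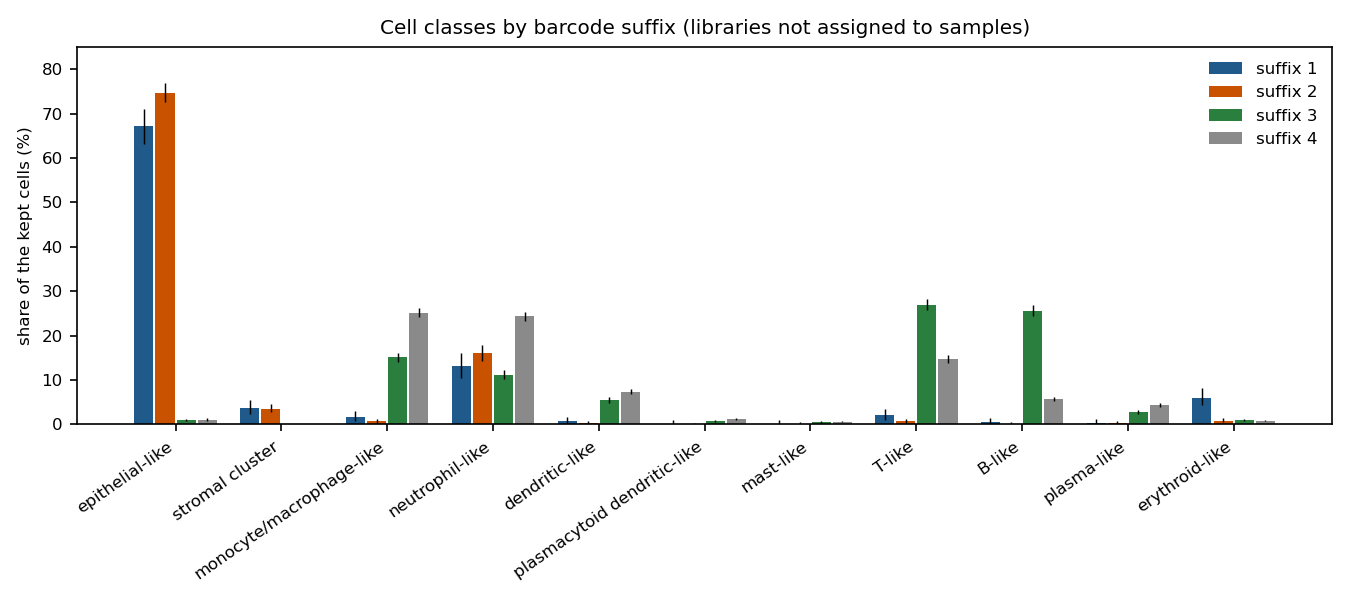
Share of kept cells (percent, linear axis from 0) in each cell class, by barcode suffix; bars are the unassigned libraries, and lines are exact 95% binomial intervals. The epithelial-like share was 67.2, 74.7, 0.941 and 1.10% for suffixes 1, 2, 3 and 4, and no suffix is assigned to a genotype or a sort.

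Of the 6 receptor and feedback genes of the EGFR family, 5 were at least 2-fold higher in epithelial-like cells than the mean of the other classes, Egfr among them. Erbb2, which pairs with Egfr, had a log2 fold of 4.33 (4.16 to 4.48), and Erbb3, a receptor for neuregulins, one of 3.25 (2.89 to 3.59). Lrig1, a negative regulator of the receptors, had 2.86 (2.51 to 3.20). Errfi1, a feedback inhibitor, had 1.94 (1.79 to 2.10), with 98.3 CPM in epithelial-like and 96.0 CPM in monocyte/macrophage-like cells. The sixth member, Erbb4, was named after its count was seen and had 3 UMIs (0.171 CPM, 0.035 to 0.501). The median log2 fold of the list was 3.05, at percentile 99.7 of 10000 random lists matched on expression.

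Ligands of these receptors divided by class. In monocyte/macrophage-like cells 4 of the 10 ligand and sheddase genes were at least 2-fold higher than in the other classes, and 3 were at least 2-fold lower. Nrg1, a neuregulin, stood at 119 CPM (116 to 123; log2 fold 4.37, 4.20 to 4.53), and Adam17, a protease that frees ligands from the membrane, had a log2 fold of 1.52 (1.39 to 1.64). Hbegf had 1.49 (1.38 to 1.58) and Ereg 1.62 (1.37 to 1.87). Egf had -1.15 (-1.46 to -0.80), Tgfa -1.54 (-1.70 to -1.36) and Btc, from 3 UMIs, -1.68 (-1.84 to -1.50). In library 3, where epithelial-like cells were too few to enter the fold, Tgfa and Btc had 0.06 and 0.10, against -1.95 and -1.35 in library 4. The median was 0.66, at percentile 99.95. Ereg had 150 CPM in the stromal cluster, and its log2 fold in monocyte/macrophage-like cells was -1.57 when unnamed clusters were counted among the other classes.

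Epithelial-like cells carried the ligands Btc (log2 fold 4.48, 4.32 to 4.61), Tgfa (4.18, 4.02 to 4.35) and Hbegf (2.71, 2.61 to 2.82), and the sheddase Adam10 (1.40, 1.30 to 1.50). Nrg1 was the only one of the 10 at least 2-fold lower, with 2 UMIs and a log2 fold of -4.10 (-4.28 to -3.88). Adam17 had -0.89 (-1.06 to -0.72), Egf -0.69 (-1.10 to -0.30) and Ereg 0.06 (-0.30 to 0.38). Egf had 1.28 and 0.87 in libraries 1 and 2, where the fold is over neutrophil-like cells alone, and -0.01 in library 4. The list median was 0.11 at percentile 16.7 in the pooled matrix, and 1.59, 1.15 and 0.37 in libraries 1, 2 and 4. The median of the EGFR ligands and sheddases was -0.29 when all other cells were summed, and -0.04 without the epithelial-like clusters of high erythroid score, where Areg had -0.20. Areg, the ligand amphiregulin, was highest in T-like cells at 689 CPM (674 to 703), against 150 CPM in monocyte/macrophage-like and 119 CPM in epithelial-like cells. The Areg log2 fold of monocyte/macrophage-like cells was 0.55 (0.50 to 0.60) in the pooled matrix, 0.84 in library 3 and -0.18 in library 4. That of epithelial-like cells was 0.17 (0.10 to 0.24), with 7.58 and 4.71 over neutrophil-like cells in libraries 1 and 2 and -1.68 in library 4.

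**Figure D2:**
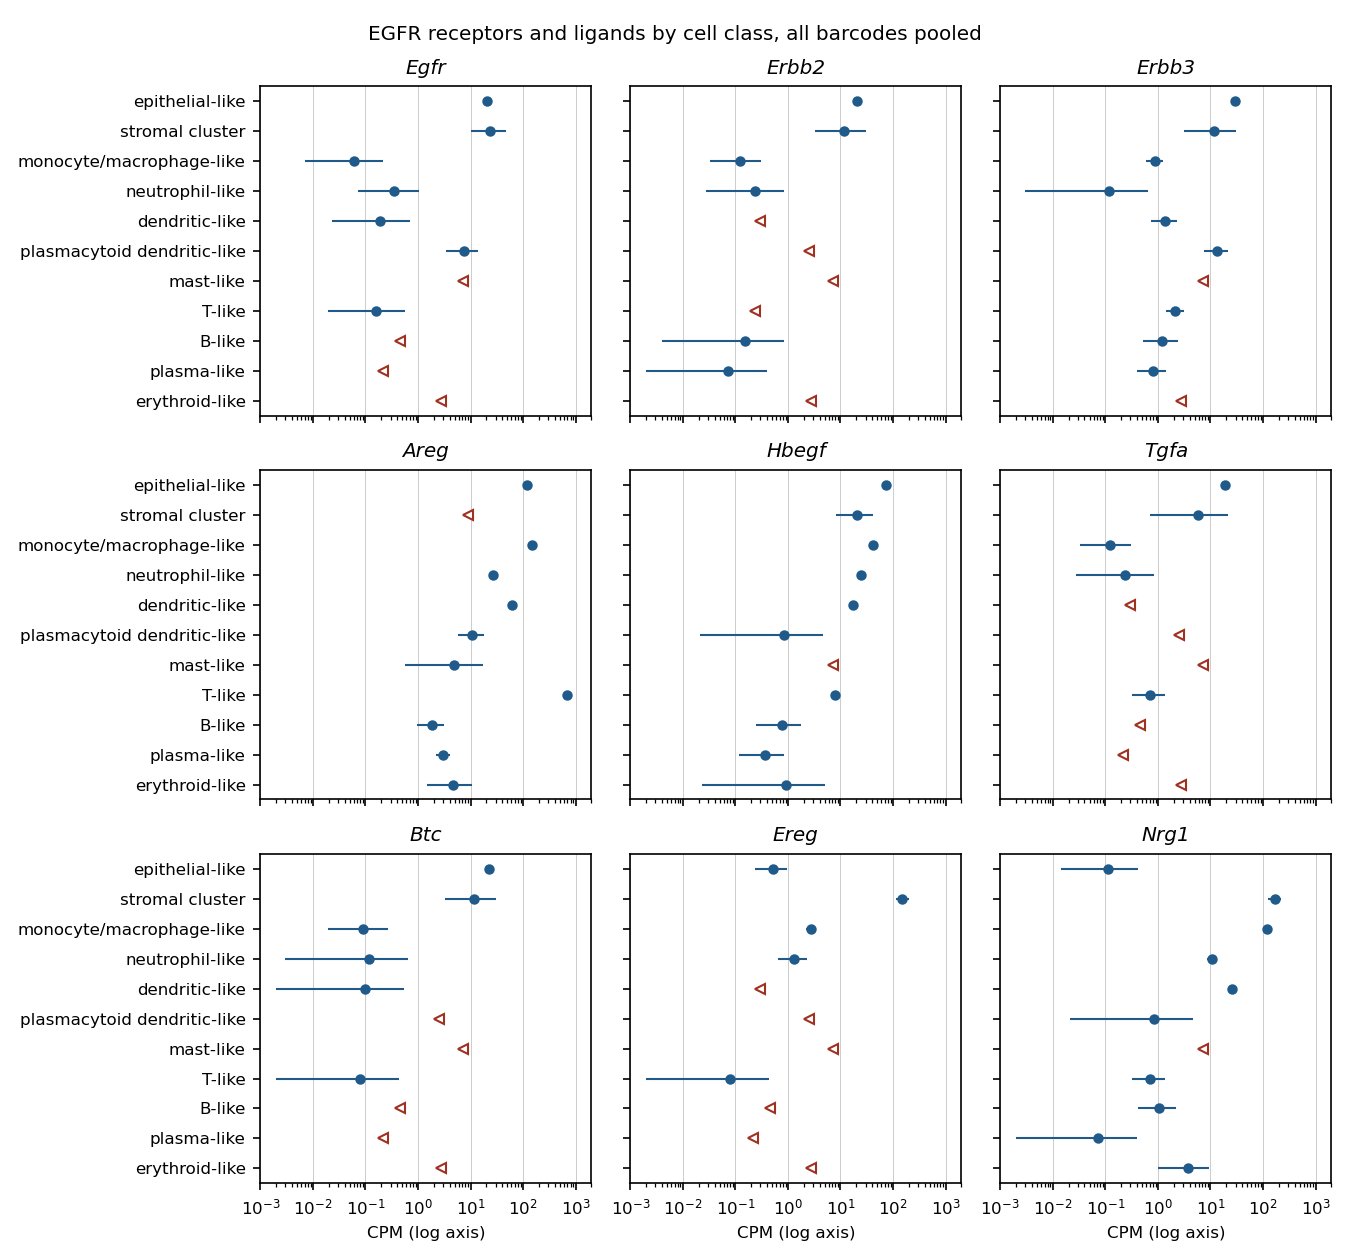
Level of 3 EGFR family receptors and 6 ligands (CPM, log axis) in each cell class of the pooled matrix; points are levels, lines exact 95% Poisson intervals, and open triangles mark the level that 3 counts allow where 0 UMIs were seen. Egfr was 20.4 CPM in epithelial-like and 0.0599 CPM in monocyte/macrophage-like cells, while Nrg1 was 0.114 CPM in epithelial-like and 119 CPM in monocyte/macrophage-like cells.

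Monocyte/macrophage-like cells stood apart in genes of myeloid immune suppression, 13 of 20 of which were at least 2-fold higher than in the other classes (median 1.88, above all 10000 random lists). Arg1, an arginine-degrading enzyme, stood at 464 CPM (log2 fold 5.54, 5.37 to 5.71). The lipid receptor Trem2 had 5.06 (4.74 to 5.41), the mannose receptor Mrc1 4.21 (4.01 to 4.42) and osteopontin, encoded by Spp1, 3.66 (3.61 to 3.73). Within the class, Arg1 and Spp1 were higher in cluster 17 and Trem2 and Mrc1 in cluster 3, as given below. The suppressive cytokines Il10 and Tgfb1 had 2.50 (2.29 to 2.71) and 1.66 (1.60 to 1.72), and Cd274, encoding PD-L1, had 0.79 (0.74 to 0.83). Ido1, a tryptophan-degrading enzyme, was lowest at -2.34 (-2.59 to -2.10).

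Antigen presentation genes were likewise higher in monocyte/macrophage-like cells, 9 of 10 at least 2-fold (median 1.76, above all 10000 random lists). The class II chains H2-Ab1 and H2-Eb1 had log2 folds of 2.09 (2.08 to 2.11) and 2.06 (2.04 to 2.07), H2-DMb1, which helps load peptides, 2.26 (2.21 to 2.32) and the costimulator Cd86 1.85 (1.79 to 1.93). Dendritic-like cells were as high or higher for H2-Ab1 (5498 against 5337 CPM), H2-Eb1 (5659 against 5563 CPM) and Cd86 (326 against 225 CPM). Ciita, the master regulator of class II genes, was lowest at 0.54 (0.47 to 0.62), with -0.25 in library 3 and 0.51 in library 4. Of the interferon response genes 4 of 10 were at least 2-fold higher (median 0.51, percentile 98.8), among them Gbp2 at 1.40 (1.33 to 1.46), Mx1 at 1.19 (0.93 to 1.44), Ifit2 at 1.13 (0.94 to 1.31) and Ifit3 at 1.10 (0.93 to 1.28). Rsad2 was lowest at -0.38 (-0.49 to -0.28) in the pooled matrix, where erythroid-like cells had 248 CPM, but had 0.35 and 0.015 in libraries 3 and 4.

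Chemokine genes were at least 2-fold higher in monocyte/macrophage-like cells for 13 of 25 and lower for 3 (median 1.03, above all 10000 random lists). Ccl24, which attracts eosinophils, had a log2 fold of 5.56 (5.43 to 5.70), the monocyte attractant Ccl8 4.74 (4.55 to 4.93), Cxcl14 3.84 (3.50 to 4.23) and Ccl9 3.64 (3.52 to 3.76). Ccl20, an attractant of Ccr6-bearing cells, had 1 UMI and a log2 fold of -2.66 (-2.78 to -2.54). When unnamed clusters counted among the other classes the median turned to -0.34, and the log2 fold of Ccl9 to -0.34. Clusters 23, 26 and 27 among them carried macrophage markers themselves.

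Of the IL-6 family 6 of 10 genes were at least 2-fold higher in monocyte/macrophage-like cells and 0 were lower (median 1.50, above all 10000 random lists). Lif had a log2 fold of 2.95 (2.72 to 3.15), Il6 itself 2.30 (2.02 to 2.58), Socs3, an inhibitor induced by STAT3, 1.81 (1.78 to 1.85) and oncostatin M, encoded by Osm, 1.78 (1.73 to 1.83). Osmr, its receptor, was lowest at -0.80 (-0.99 to -0.59), with 0.14 in library 3 and -0.74 in library 4. Neutrophil-like cells were higher than monocyte/macrophage-like cells for Osm (909 against 461 CPM) and Socs3 (1115 against 811 CPM). Il6 was at 94.98 CPM in mast-like and 86.8 CPM in monocyte/macrophage-like cells. Of the named classes, monocyte/macrophage-like cells were highest for Lif, at 43.96 CPM against 14.63 CPM in T-like cells. With unnamed clusters counted among the other classes the median fell to 0.08, inside the range of random lists, and Il6 in monocyte/macrophage-like cells to -0.998. Those clusters included cluster 10, with Il6 at 2439 CPM, and clusters 23, 26 and 27, which themselves carried macrophage markers. Of the angiogenesis genes 4 of 9 were at least 2-fold higher (median 0.96, percentile 99.9). Vegfa, a growth factor for vessels, had 3.51 (3.41 to 3.60) at 335 CPM, Pdgfb 2.76 (2.59 to 2.92), Pgf 2.35 (2.20 to 2.49) and Pdgfa 1.16 (0.99 to 1.33). Angpt1 had 0 UMIs, allowing up to 0.0898 CPM, against a mean of 10.0 CPM elsewhere that rests on 44 UMIs and on mast-like cells at 87.9 CPM. In libraries 3 and 4, without mast-like cells in the mean, its log2 fold was -0.21 and -0.20.

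Neutrophil-like cells led the IL-1 family, with 6 of 12 genes at least 2-fold higher than in the other classes and 4 lower (median 1.99, above all 10000 random lists). Il1b, an inflammatory cytokine, reached 30992 CPM (30874 to 31110; log2 fold 3.83, 3.83 to 3.84). Nlrp3, a sensor that drives its processing, had 5.10 (5.02 to 5.17), the receptor chain Il1rap 4.75 (4.53 to 4.96), the decoy receptor Il1r2 4.15 (4.11 to 4.21) and the receptor antagonist Il1rn 3.90 (3.87 to 3.93). Il1rl1, the IL-33 receptor, was lowest at -2.72 (-3.06 to -2.37) against a mean that includes 451 CPM in mast-like cells. In libraries 1 to 4, where mast-like cells did not enter the mean, Il1rl1 had 2.83, -0.12, -0.41 and -0.63. In monocyte/macrophage-like cells the same list had a median of 0.04 at percentile 70.2, with 4 genes higher and 4 lower, and alternatives moved that median to either side of 0. Il1a had 2.14 (2.11 to 2.17), Il1rn 1.70 (1.67 to 1.72) and Il1b 1.22 (1.22 to 1.23) there, and Il1rl1 -4.99 (-5.29 to -4.69).

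Suppression genes also stood apart in neutrophil-like cells, where 8 of 20 were at least 2-fold higher and 5 lower (median 0.14, percentile 99.9). Arg2, a second arginase, had a log2 fold of 5.57 (5.43 to 5.71) at 575 CPM, Wfdc17 4.18 (4.14 to 4.21), Ptgs2, which makes prostaglandins, 3.60 (3.57 to 3.63) and Cd274 2.79 (2.73 to 2.85) at 794 CPM. Tgfb1 had 0.42 (0.33 to 0.50), Il10 -0.61 (-1.07 to -0.22), Arg1 -1.18 (-1.37 to -1.003) and Trem2, the lowest, -1.95 (-2.34 to -1.62). The central 95% of random lists matched on expression ran from -2.21 to -0.49 in this class, so a median near 0 ranked high. The median turned to -0.21 with all other cells summed and to -0.15 with unnamed clusters counted, above the central 95% of random lists in both.

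The myeloid classes, the lineage of the deletion, were also set against each other. The IL-1 list was lower in monocyte/macrophage-like than in neutrophil-like cells (median log2 ratio -1.41, percentile 0.02), with 7 of 12 genes at least 2-fold lower and 1 higher. Il1rap had -3.63 (-3.76 to -3.50) and Il1b -1.57 (-1.58 to -1.57), while Casp1, the protease that matures IL-1 beta, had 1.18 (0.99 to 1.37). Chemokines were higher in monocyte/macrophage-like cells (median 1.34, percentile 98.6; 13 of 25 at least 2-fold higher, 5 lower), among them Cxcl14 (4.85, 4.41 to 5.38), Ccl7 (4.75, 4.34 to 5.22), Ccl17 (4.46, 4.03 to 5.00) and Ccl8 (4.37, 4.14 to 4.62). Cxcl2, a neutrophil attractant, had -2.27 (-2.28 to -2.27). The chemokine median left the range that stands apart under several alternatives, with 0.71 when library 3 was left out and 0.48 with 10 CPM added.

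The suppression list did not stand apart between the myeloid classes (median 0.76, percentile 61.8; 0.78 with 1 gene at its bound). The central 95% of random lists ran from -0.24 to 1.57. Of its 20 members 7 were at least 2-fold higher in monocyte/macrophage-like cells and 3 lower. Trem2 had a log2 ratio of 4.82 (4.48 to 5.25), Mrc1 4.41 (4.18 to 4.68), Arg1 4.16 (4.00 to 4.36), Ptges, a prostaglandin E synthase, 3.28 (2.77 to 3.82), Il10 2.51 (2.15 to 2.93) and Tgfb1 1.01 (0.94 to 1.08). Arg2 had -3.10 (-3.17 to -3.03) and Cd274 -1.43 (-1.48 to -1.39). Angiogenesis genes had a median of 1.65 (percentile 96.0; 5 of 9 at least 2-fold higher), with Pdgfa at 4.48 (4.04 to 5.02), Pdgfb at 3.73 (3.32 to 4.26), Pgf at 3.31 (2.89 to 3.81), Vegfb at 2.80 (2.37 to 3.31) and Vegfa at 1.65 (1.56 to 1.76). Angpt1 had 0 UMIs in both classes. EGFR ligands had a median of 0.71 (percentile 86.5), with Nrg1 at 3.37 (3.11 to 3.67), Areg at 2.46 (2.29 to 2.66), Adam10 at 1.41 (1.27 to 1.58), Adam17 at 0.89 (0.76 to 1.05), Hbegf at 0.72 (0.53 to 0.93) and Ereg at 0.71 (0.22 to 1.32; -0.14 in library 3 and 0.88 in library 4). The angiogenesis median was 2.80 and stood apart when genes with few UMIs were left out.

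**Figure D3:**
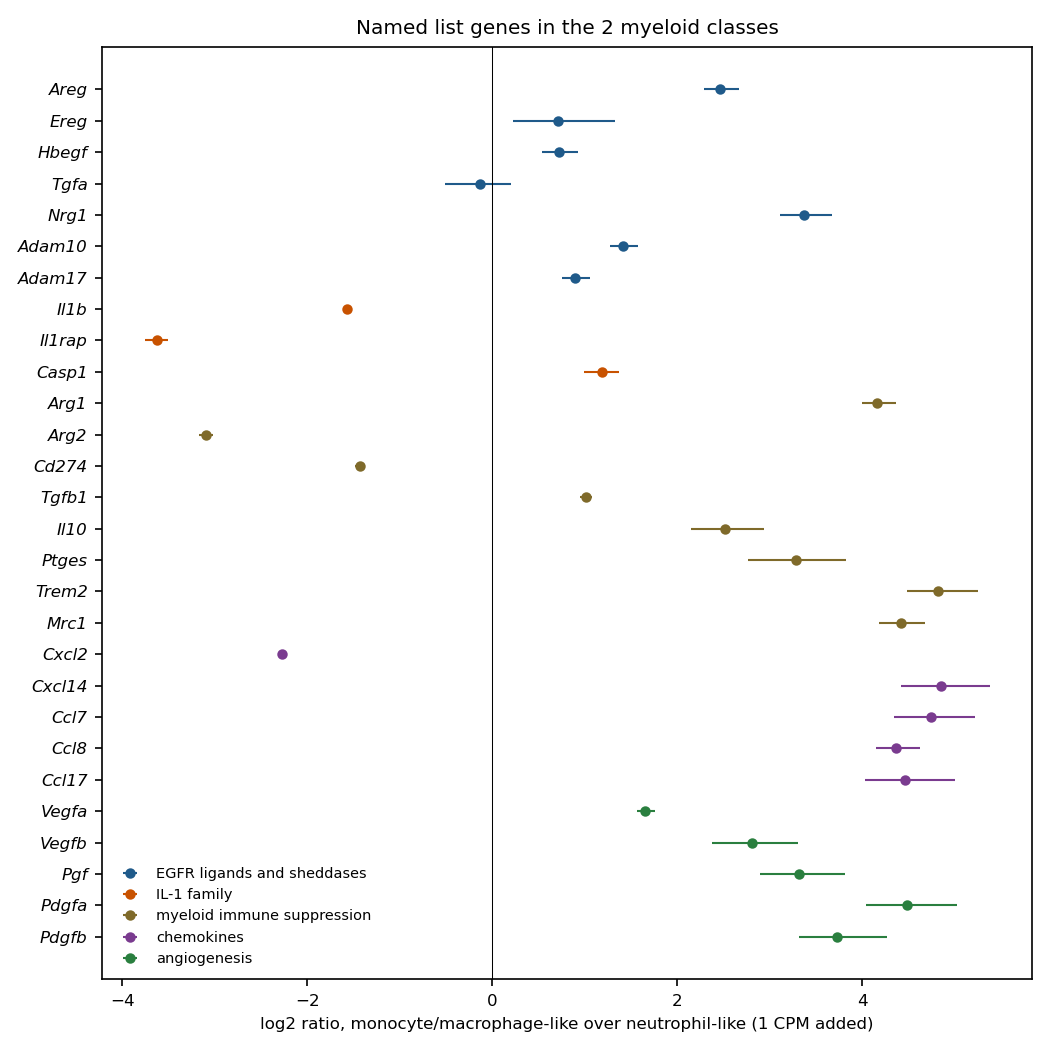
Log2 ratio of monocyte/macrophage-like over neutrophil-like CPM (1 CPM added) for the named genes of 5 lists, coloured by list; points are pooled values and lines 95% ranges over Poisson redraws. Il1rap (-3.63), Arg2 (-3.10) and Cxcl2 (-2.27) lie to the neutrophil-like side, and Cxcl14 (4.85) and Trem2 (4.82) to the other.

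T-like cells stood apart in checkpoint and costimulation genes, 9 of 13 at least 2-fold higher and 1 lower (median 4.18, above all 10000 random lists). The costimulators Icos and Tnfrsf4 had log2 folds of 7.17 (6.89 to 7.43) and 6.30 (6.17 to 6.43), and the inhibitory receptors Ctla4 and Pdcd1 had 6.05 (5.88 to 6.22) and 5.78 (5.57 to 5.99). Entpd1 was lowest at -2.07 (-2.23 to -1.93). Effector genes were at least 2-fold higher for 12 of 14 (median 3.95, above all 10000 random lists). They included the cytokines Il17a (8.599, 8.31 to 8.88), Ifng (7.29, 7.15 to 7.42), Il22 (7.05, 6.94 to 7.14) and Il17f (6.98, 6.87 to 7.08), while Tnf was lowest at -3.05 (-3.22 to -2.89). Proliferation genes were higher in T-like cells (median 1.34, percentile 99.99; 8 of 10 at least 2-fold), with Top2a at 2.29 (2.12 to 2.47), Cenpf at 1.92 (1.70 to 2.13), Mki67 at 1.72 (1.58 to 1.88), Tpx2 at 1.45 (1.19 to 1.74) and Cdk1 at 0.96 (0.66 to 1.25). That result did not hold up: the median was -1.30 under the stricter cell filter and -0.76 with doublets kept.

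Within T-like cells, 626 cells of a regulatory-T-like cluster, named by markers such as Foxp3, were set against the other 1691. Checkpoint and costimulation genes were higher in the former, 10 of 13 at least 2-fold and 0 lower (median log2 ratio 1.68, above all 10000 random lists). Tnfrsf9 had 3.02 (2.94 to 3.10), Tnfrsf4 2.74 (2.67 to 2.81), Tnfrsf18 2.13 (2.05 to 2.20) and Tigit 1.98 (1.36 to 2.57), while Btla had -0.26 (-0.67 to 0.11), with -0.48 in library 3 and 0.38 in library 4. Effector genes were lower, 12 of 14 at least 2-fold (median -2.58, percentile 0; -2.52 with the 4 genes at 0 on 1 side set at their bound). Il22, a cytokine of type 3 responses, had 0 UMIs, allowing up to 1.00 CPM, against 186 CPM in other T-like cells, and Gzmb, a granule protease, was higher at 1.75 (1.64 to 1.85). Unnamed cluster 6 (533 cells, markers of CD8 T and NK cells) was not among these other cells. Nor was unnamed cluster 29 (50 cells, markers of T cells and neutrophils), with Gzmb among its leading genes. The Gzmb ratio therefore does not cover all cells with T cell markers. Library 3 alone gave checkpoint and effector medians of 2.48 and -1.97 and library 4 gave 0.97 and -3.40. The other T-like cells included cluster 21, 699 cells with CD8 T markers led by Dapl1 and Lef1. It had 590 cells in library 3 and 105 in library 4, so the cells compared differed between these libraries. Without library 3 the checkpoint median was 0.95, with 6 checkpoint genes and 0 effector genes at least 2-fold higher.

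Epithelial-like cells carried Wnt target and regenerative genes, 15 of 18 at least 2-fold higher and 1 lower (median 4.96, above all 10000 random lists). The secreted Wnt inhibitors Wif1 and Notum had log2 folds of 8.41 (8.29 to 8.53) and 7.49 (7.38 to 7.59), the feedback inhibitor Nkd1 7.96 (7.53 to 8.28) and the progenitor factor Sox9 7.01 (6.79 to 7.20). Cd44, an adhesion molecule of many immune cells, was lowest at -2.18 (-2.27 to -2.11). Absorptive genes were at least 2-fold higher for 8 of 9 (median 3.003, percentile 99.99; 3.26, 0.94 and 4.72 in libraries 1, 2 and 4), with the hormone precursor Guca2a at 6.81 (6.59 to 7.01), Saa1 at 6.38 (6.24 to 6.52), the mucin Muc3 at 5.67 (5.43 to 5.88) and the carbonic anhydrase Car1 at 5.15 (4.80 to 5.49). Alpi had 1 UMI (0.08, 0.00 to 0.23), and the median was 5.15 with the 2 genes counted at 0 elsewhere set at their bound. Without the epithelial-like clusters of high erythroid score the absorptive differentiation list had a median of 1.48, with 5 genes at least 2-fold higher, Saa1 at 1.48 and Car1 at 3.34, and Aurkb had 0.67. All 10 proliferation genes were at least 2-fold higher (median 2.27, percentile 99.98), from Cenpf at 3.02 (2.78 to 3.25), Ccnb1 at 2.97 (2.66 to 3.33), Ccnb2 at 2.94 (2.65 to 3.23) and Birc5 at 2.64 (2.42 to 2.85) to Aurkb at 1.30 (0.91 to 1.74).

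No cluster could be named fibroblast-like, so the lists fixed for that class were read in the unnamed stromal cluster, a choice made after seeing the data. Its matrix and cancer-associated fibroblast genes were at least 2-fold higher for 20 of 22, 16 of them with at least 10 UMIs (median 4.78, above all 10000 random lists; 5.37 with 1 gene at its bound). Sparc, a matrix protein, had a log2 fold of 10.70 (10.42 to 10.97), the morphogen Bmp4 8.94 (8.72 to 9.15), periostin, encoded by Postn, 8.24 (7.93 to 8.52) and the collagen Col12a1 7.84 (7.49 to 8.14). Mmp9, from 3 UMIs, was lowest at -2.84 (-6.13 to -1.71). Angiogenesis genes had a median of 1.11 (percentile 95.2; 6 of 9 at least 2-fold, 5 of them with at least 10 UMIs), with Angpt2 at 5.29 (4.68 to 5.75), Pdgfb at 4.43 (4.00 to 4.74), Vegfc at 3.89 (2.76 to 4.72), Pdgfa at 2.83 (2.39 to 3.21) and Vegfa at -0.32 (-1.16 to 0.26). In library 2 the angiogenesis median was 2.16, with Angpt2 at 2.16 and Vegfa at -3.70. The cluster drew 22 and 61 cells from libraries 1 and 2 and 0 from libraries 3 and 4, which allow up to 0.0672 and 0.0407% there. The angiogenesis median stood apart at 1.56 without library 1 and 2.83 without library 4.

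In the stromal cluster 4 of the 10 IL-6 family genes were at least 2-fold higher (median 0.34, percentile 53.2). Library 2, the only one with at least 50 such cells, gave a median of 1.38 over its epithelial-like and neutrophil-like cells. Il11, a cytokine of the family, had 7.02 (6.57 to 7.36), the receptor chains Osmr, Il6st and Il11ra1 had 6.58 (6.18 to 6.93), 3.59 (3.28 to 3.85) and 2.75 (1.98 to 3.30), and Il6 had -0.96 (-2.74 to 0.02) from 4 UMIs. In library 2 alone Il11 had 4.62 and Il6 2.86, opposite in sign to its pooled value. With genes at 0 UMIs set at the level 3 counts allow, 8.83 CPM, 1 gene was lower, Osm, against a mean of 166 CPM in the named classes. Of the chemokines 10 of 25 were at least 2-fold higher, 9 of them with at least 10 UMIs, among them Ccl11 at 9.43 (9.22 to 9.60), Cxcl12 at 8.59 (7.97 to 9.39), Cxcl5 at 5.61 (5.42 to 5.78) and Cxcl14 at 5.02 (4.68 to 5.30), and with genes at 0 set at that level 12 were lower. Cxcl5 had 1.52 in library 2. Cxcl3, at 0 UMIs, was likewise limited to 8.83 CPM against 660 CPM elsewhere. The chemokine median was -1.39 (percentile 0.01), but 0.52 with the 7 genes at 0 on either side so set, so it gives no direction at this depth.

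**Figure D4:**
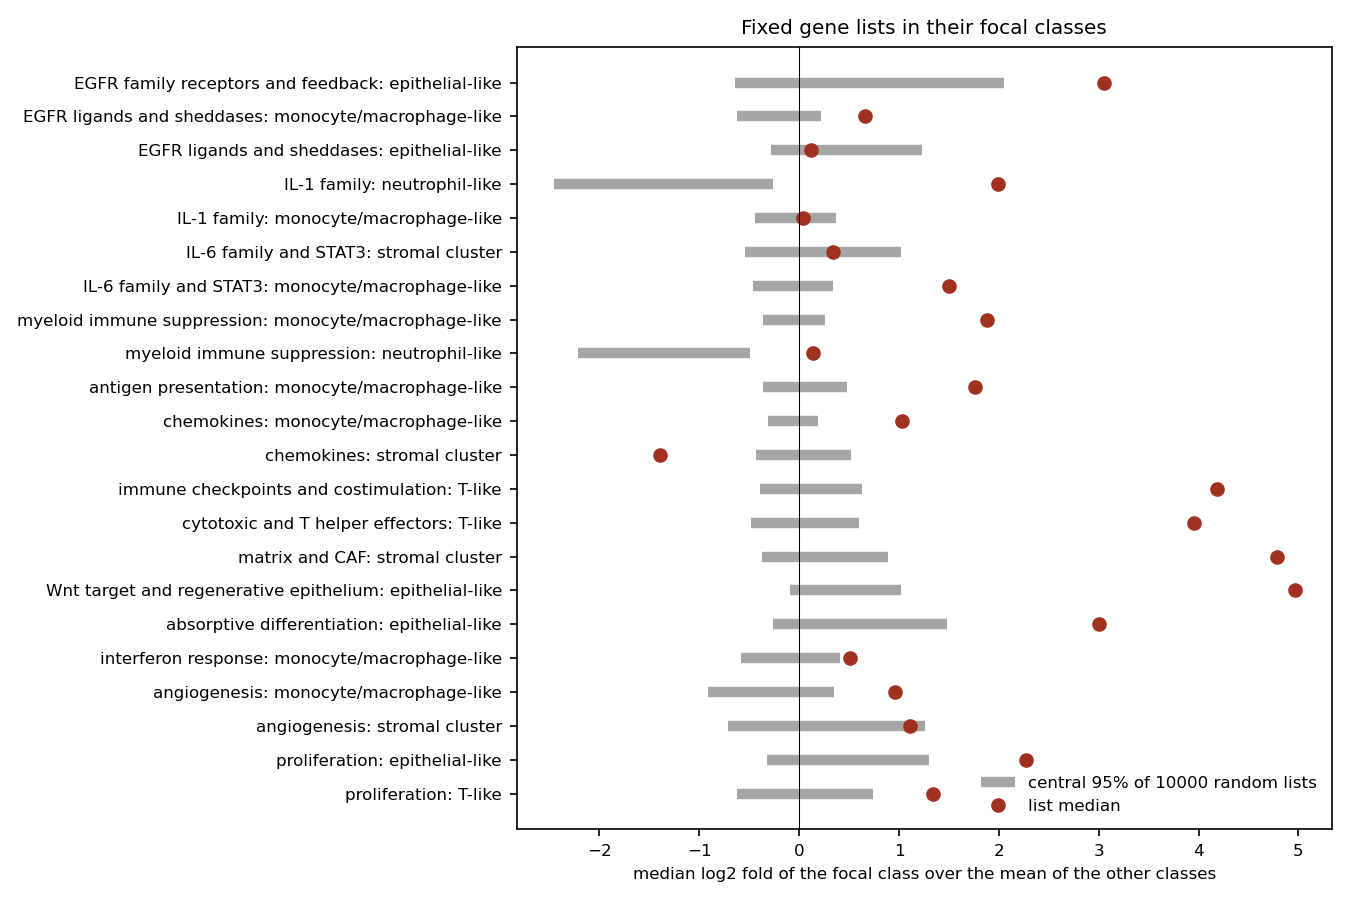
Median log2 fold of each fixed gene list in its focal class over the mean of the other classes (points), with the central 95% of 10000 random lists matched on expression (grey bars). The points run from -1.39 for chemokines in the stromal cluster, whose sign depends on genes at 0 UMIs, to 4.96 for Wnt target genes in epithelial-like cells.

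Genes induced by tissue dissociation also differed between classes. In neutrophil-like cells 6 of the 10 stress genes were at least 2-fold higher than elsewhere (median 2.02, percentile 99.96), as were 6 in monocyte/macrophage-like cells (1.16, percentile 99.98). The median was -1.70 in T-like (percentile 0.52), -2.05 in plasmacytoid-dendritic-like (0.1) and -2.74 in erythroid-like cells (0.06). It did not stand apart in dendritic-like (-0.11), mast-like (-0.81), epithelial-like (-0.89), B-like (-1.26) or plasma-like cells (-2.89). The IL-1 list was read in both myeloid classes with high stress genes, and the IL-6 and chemokine lists in monocyte/macrophage-like cells.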

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

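The 6 results here were singled out because a fixed list gene stood, in an unnamed cluster outside the class comparisons, above its level in each named class; of the tests weighed, those of random pairs, of free neutrophil RNA and of the Ccl8 level in cluster 27, and of other clusters as a source of Il6 in cluster 10, were chosen only after the result was seen.

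Ccl5, an attractant of T cells, reached 7411 CPM (7316 to 7508) in cluster 6, 533 cells with markers of CD8 T and NK cells, against 1000.4 CPM in dendritic-like cells. Gzma, a granule protease of cytotoxic cells, reached 2754 CPM (2594 to 2922) in cluster 29, 50 cells with markers of T cells and neutrophils, against 192 CPM in T-like cells. Of these 50 cells 49 came from library 4, so the value rests on that library. Mki67, a marker of dividing cells, reached 637 CPM (613 to 663) in cluster 26, 160 cells led by Top2a with markers of macrophages and B cells and a median of 23179.5 UMIs, against 117 CPM in T-like cells. Errfi1 reached 475 CPM (412 to 545) in cluster 23, 303 cells with a median of 966 UMIs, against 98.3 CPM in epithelial-like cells. Cell pairs in these 4 clusters were not tested.

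Ccl8, a monocyte attractant, reached 884 CPM (862 to 907) in cluster 27, against 320 CPM in monocyte/macrophage-like cells. Its 408 cells, with markers of both macrophages and neutrophils, were 70 from library 3 and 338 from library 4, where an assumed loading rate gives 5.40 and 53.5 random pairs of those classes. Free neutrophil RNA as the source of the neutrophil markers was not decided. Cluster 27 had been set apart by these markers, with a neutrophil score of 4.61, so an excess over cluster 3 was built in. In library 4 the neutrophil markers stood a median log2 of 5.55 above those of cluster 3, with S100a8 at 12505 against 265 CPM. The lowest and highest of the 7 markers were at 2.68 and 5.96. Pairs of cluster 3 macrophages, at that cluster's mean Ccl8, with neutrophils were argued against for the Ccl8 level in library 4, a log2 of 0.67 (0.62 to 0.72) above cluster 3, but not in library 3, at -0.079 (-0.19 to 0.03). For the shared markers such pairs, attached, engulfed or in 1 droplet, may account and stay open, as their mix lay a median of 0.196 from cluster 27 over 100 list genes (cluster 3 alone 0.476); random pairs of any macrophage, whose mix lay 0.530 away, cannot be told apart, since the clustering may itself set that distance and the median log2 of -3.33 of the 11 genes that part clusters 17 and 3, and no biological explanation was tested.

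Il6, an inflammatory cytokine, reached 2439 CPM (2250 to 2639) in cluster 10, against 94.98 CPM in mast-like cells. The 63 cells of the cluster were led by Gata2, Il4 and Mcpt8, genes of basophils, although no basophil list was fixed. RNA or cells from elsewhere were argued against, as the highest upper bound of Il6 in any other cluster was 224.2 CPM. A source in 1 library was argued against too, since Il6 lay above that bound in 4 of 4 libraries, at 2268, 2708, 2198 and 2864 CPM. Induction during tissue digestion stays open, with the stress genes Junb at 3678 and Jun at 2981 CPM there, and no biological explanation was tested, as the libraries have no groups.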

How the results depend on the processing

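Doublets at the expected rate removed, unnamed clusters counted as classes, leaving out the erythroid-like class, leaving clusters of high erythroid score unnamed and the lists read in the stromal cluster were tests chosen only after the data were seen. No paired analysis was possible because the libraries are not assigned to samples and each group has 1 sample. Of 547 alternative list medians 512 kept their direction and side of the limits, 6 lost and 5 gained their place outside the random lists, and 24 changed sign; of 3063 named-gene folds 1960 stayed inside the counting interval, 1093 moved and 10 changed sign; of 60 class shares 27 moved. Unless stated, the cause was not tested. Depth limits small clusters, where 0 UMIs allow up to 8.83 CPM in the stromal cluster and 11.9 CPM in cluster 10.

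The IL-1 family median of monocyte/macrophage-like cells (0.04) never stood apart and was -0.074 under the stricter filter and with list genes as features, -0.121 and -0.114 at resolutions 0.5 and 2, -0.237 with 4000 variable genes, -0.161 with doublets at the expected rate removed, -0.375 without abundant genes in the totals, -0.035 with other cells summed, -0.143 with unnamed clusters, -0.088 without the erythroid-like class and -0.058 to 0.046 with a library left out. EGFR ligands and sheddases in epithelial-like cells (0.11) were at -0.11 under the stricter filter, -0.089 without abundant genes, -0.29 with other cells summed, -0.038 without clusters of high erythroid score and -0.052 to 0.429 with a library left out.

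The median for proliferation in T-like cells (1.34) was -1.297 under the stricter filter (Mki67 -0.948, Top2a -0.314, Tpx2 -1.566, Cenpf -1.38) and -0.761 with doublets kept (Mki67 -0.495, Tpx2 -0.995, Cenpf -0.693). That for chemokines in monocyte/macrophage-like over neutrophil-like cells (1.34) no longer stood apart at resolution 2 (1.25), with 4000 variable genes (1.197), with doublets at the expected rate removed (1.054) or with 10 CPM added (0.478), and ranged from 0.713 to 2.053 with a library left out. That for angiogenesis in the same comparison (1.65) was 2.80 with only list genes of a mean of at least 10 UMIs. In the stromal cluster the IL-6 family and STAT3 list (0.34) was at -0.111 without abundant genes, and angiogenesis (1.11) at 2.201 with other cells summed, 1.434 with unnamed clusters and 1.046 to 2.827 with a library left out. The list of myeloid immune suppression in neutrophil-like cells (0.14) was -0.213 with other cells summed and -0.153 with unnamed clusters. With unnamed clusters, monocyte/macrophage-like cells had medians of 0.079 for the IL-6 family and STAT3 list and -0.337 for chemokines, with Ereg at -1.573, Il6 at -0.998 and Ccl9 at -0.337.

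The Egfr log2 fold of epithelial-like cells (3.49) was 2.622 under the stricter filter, 4.343 and 1.48 with 0.1 and 10 CPM added, 4.155 with other cells summed, 2.821 with unnamed clusters, 2.97 without clusters of high erythroid score, 4.424 after thinning and 3.245 to 4.307 with a library left out. The added CPM moves it by construction. Of the cell classes in the matrix, the named cells numbered 6187 to 11959 with a library left out.

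Counts of genes at least 2-fold higher moved by over 1.5 times as follows. Absorptive genes gave 5 (from 8) under the stricter filter, with 10 CPM added and without clusters of high erythroid score. Proliferation in T-like cells (8) gave 0 under the stricter filter and with doublets kept, 2 at resolution 0.5, 1 with 4000 variable genes and with unnamed clusters, and 4 with 10 CPM added. Interferon genes (4) gave 1 with 10 CPM added and with unnamed clusters, and 2 with other cells summed or without library 3. EGFR ligands over neutrophil-like cells (3) gave 5 with 0.1 CPM added or without library 4, and IL-1 genes (1) gave 0 with 10 CPM added or without abundant genes. Regulatory-T-like effectors (1) gave 2 at resolution 0.5 and 0 without library 3, and checkpoints (10) gave 6 without library 3. Matrix genes (16) gave 7 when only genes with a mean of at least 10 UMIs over the named classes were kept, which drops genes by construction. With unnamed clusters the IL-6 family (6) gave 3 and angiogenesis (4) gave 2 in monocyte/macrophage-like cells. Without library 1 stromal chemokines (9) gave 5 and angiogenesis (5) gave 2.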

Other observations

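The comparisons between clusters and the regulatory-T-like values below were tests chosen only after the data were seen; the test of Egfr in plasmacytoid-dendritic-like cells was written down before its result.

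Monocyte/macrophage-like cells held a pair of clusters with contrasting list genes. Cluster 17 (1417 cells, led by Chil3 and Inhba) was at least 2-fold higher than cluster 3 (1139 cells, led by Pf4 and C1qa) for 53 of 171 list genes and lower for 39. Nos2, which makes nitric oxide, was 107 against 4.12 CPM, Ptges 36.5 against 1.37 CPM, Il6 163 against 10.8 CPM, Lif 83.1 against 5.07 CPM and Areg 281 against 20.3 CPM. The mannose receptor Mrc1 was 30.9 against 451 CPM and the matrix protease Mmp2 1.86 against 88.2 CPM. Of the 20 suppression genes 9 were at least 2-fold higher in cluster 17 and 4 lower. Arg1 was at 801 against 129 CPM and Spp1 at 1433 against 224 CPM, while Trem2 was at 81.4 against 242 CPM. Among neutrophil-like cells, cluster 12 had more Tnf (1614 against 276 CPM) and Havcr2 (54.0 against 9.25 CPM) than cluster 11, which was led by granule genes such as Ngp and Camp, and less Anxa1 (254 against 872 CPM). Of the 10 dissociation stress genes 5 were at least 2-fold higher in cluster 12 and 0 lower, beside 29 higher and 5 lower of all 116 list genes compared. Atf3 was at 853 against 322 CPM and Hspa1a at 64.7 against 21.4 CPM, while Fos was lower, at 555 against 960 CPM. Between clusters 17 and 3, 1 of the 10 was higher and 2 lower, Hspa1a at 228 against 671 CPM.

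Epithelial-like cluster 7 had more of the stem cell gene Lgr5 than cluster 1 (79.7 against 4.07 CPM), with Znrf3 at 74.3 against 5.77 CPM, Rnf43 at 196 against 29.2 CPM and Axin2 at 277 against 63.4 CPM. Egfr was lower in cluster 7, at 10.1 against 48.8 CPM, from 84 and 144 UMIs. Of the 18 Wnt target and regenerative genes 10 were at least 2-fold higher in cluster 7 and 2 lower, Ly6a at 257 against 1418 CPM and Anxa1 at 219 against 1524 CPM. The pair was picked by the leading genes Wif1 and Saa1, members of the Wnt target and absorptive lists. Nkd1 and Notum also led cluster 7 and, with Wif1, are counted among the 10. The contrast in Wnt target and absorptive genes was therefore partly built in. Library 2 gave 444 of the 490 cells of cluster 7 and 322 of the 627 of cluster 1, and their median depths were 15800.5 and 1930 UMIs. Some genes high in myeloid cells were also lower in cluster 7, with Arg1 at 1.69 against 57.6 CPM, Ccl8 at 0.241 against 81.0 CPM, Ccl6 at 2.77 against 76.0 CPM, Il1a at 1.45 against 43.7 CPM and Mrc1 at 3.25 against 21.4 CPM. Others were higher there, with Spp1 at 44.9 against 8.82 CPM, Thbs1 at 123 against 27.1 CPM and Inhba at 16.3 against 0.339 CPM. Of 16 myeloid immune suppression genes compared, 2 were at least 2-fold higher in cluster 7 and 8 lower. Of all 147 list genes compared, 34 were higher and 58 lower. Cluster 1 had an erythroid score of 6.23 beside its epithelial score of 6.56. RNA of other cells in cluster 1 was not tested. Of the stress genes 2 were higher in cluster 7 and 0 lower. Absorptive genes were lower in cluster 7, with Car1 at 11.6 against 241 CPM and Muc3 at 0.602 against 109 CPM. Regulatory-T-like cells had 1578 CPM of Areg (1534 to 1624) against 412 CPM (400 to 425) in other T-like cells, 257 against 20.5 CPM of Il1rl1 and 72.7 against 7.46 CPM of Il10. Areg in regulatory-T-like cells was 817 CPM in library 3 and 2023 CPM in library 4. Cluster 10, which had the highest Il6, also carried 3405 CPM of Osm, 19809 CPM of Ccl3, 43886 CPM of Ccl4 and 685 CPM of Il13.

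Class shares differed between libraries, and no library is assigned to a sort or a genotype. Libraries 1, 2, 3 and 4 held 67.2, 74.7, 0.941 and 1.10% epithelial-like cells, 18.7, 18.7, 88.6 and 83.6% named immune cells, 13.1, 16.0, 11.2 and 24.3% neutrophil-like cells, and 1.68, 0.765, 15.1 and 25.2% monocyte/macrophage-like cells. T-like cells numbered 12, 12, 1205 and 1088, and B-like cells made up 0.505, 0.177, 25.6 and 5.70%.

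Egfr was also seen in plasmacytoid-dendritic-like cells, with 9 UMIs in 8 of 128 cells (7.45 CPM, 3.41 to 14.1), at 17.7 CPM in library 3 and 3.55 CPM in library 4. A candidate explanation is RNA from epithelial cells, whose 10 markers would then accompany Egfr as they do in epithelial-like cells. The markers gave 191 UMIs against 5364 so predicted, a ratio of 0.0356 (0.0184 to 0.0791), which argues against it. Of those 191 UMIs 126 were Cdh1 and 35 Epcam, and Krt8 gave 1. Expression in a few such cells stays open at 9 UMIs, and no biological explanation was tested.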
